A study of Mus musculus with 10 samples.

How the data were processed

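RNA sequencing of whole mouse liver was compared between 5 mice given napabucasin and 5 given the vehicle, 1 library per group and replicate. Napabucasin (BBI608) is a small quinone described as an inhibitor of STAT3-driven transcription. Per the labels' protocols it was given by gavage at 20 mg per kg body weight once a day for 7 days, and the vehicle was 1% sodium carboxymethyl cellulose. The labels call the libraries biological replicates. Polyadenylated RNA was selected, fragmented and primed with random hexamers, per the labels' protocols.

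The deposited counts are whole-number reads per gene, not normalized. Per the submitters' processing notes, the tools were CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3, and the genome build was GRCm38 (mm10). The strand setting and the annotation release are not given in the sources used here, so overlapping and antisense genes were not separated. The deposited FPKM values were made by the authors from the counts and gene lengths. In each library their denominator equalled a median-of-ratios size factor multiplied by the geometric mean of the library totals, checked on the values. The authors' group mean FPKM columns were not used in a test. Gene symbols and coordinates were taken as the deposited count table gives them. Near-identical genes, such as Trbc1 and Trbc2, the Gbp genes and Saa1 and Saa2, can share reads, and their separate values are uncertain.

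The count table holds 54532 genes, of which 26567 had a count above 0. Library totals ran from 14124484 to 17759967 counts. Counts were tested in R 4.3.3 with edgeR 4.0.16: the filterByExpr filter, which left 14244 genes, TMM normalization, and the robust quasi-likelihood F test with treatment as the only term. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors of log2 fold changes are those implied by the F statistic, and CPM values use TMM library sizes. The common biological coefficient of variation was 0.325. The p-values measure the spread between these libraries.

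Gene lists, 62 in all, were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. They cover drug and xenobiotic pathways, hepatic metabolism, stress, immune and stromal genes, liver cell types, other tissues and RNA quality. The 58 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Of 1330 list names, 7 were not matched in the table. Camera was repeated with the correlation estimated from the data, and fry was run in its directional and mixed forms. A score per list and library, the mean of centred log2 CPM over members, was compared between groups by an exact two-sided permutation test over 252 label assignments, whose smallest p is 0.0079. These tests take no account of pairs; exchanging labels within 5 pairs gives 32 assignments, with a smallest p of 0.0625.

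Named genes are the 10 largest rises and falls past the threshold, and the 5 of each among abundant genes. With fewer than 10 in a direction, the list was filled to 5 by smallest p among genes with a mean of at least 1 CPM. Stat3, Nqo1, Socs3, Por, Cyp3a11, Cyp2b10, Cyp1a1 and Cyp1a2 were named whatever their p, and each list described gave up to 4 members with the smallest p. One gene that the rule names is not reported here. Which lists were described beyond those past the threshold was decided after their values were seen.

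The alternatives were size-factor or no normalization, other filters, a non-robust test, DESeq2 1.42.0, limma-voom with quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5 and on log2(FPKM + 1) without that filter, a replicate block, 1 surrogate variable (sva 3.50.0), each library left out, and protein-coding genes only. The labels do not say what equal replicate numbers share. Deviations from the group means of same-numbered libraries correlated at 0.154, 0.227, 0.208, 0.270 and 0.278 for numbers 1 to 5, all above 0.1, so the numbers were treated as pairing the samples from the data alone. Only 6 of the 10 libraries correlated best with their own number: vehicle replicate 1 correlated at 0.281 with napabucasin replicate 5, and vehicle replicate 2 at 0.241 with napabucasin replicate 1. With the replicate block 0 genes passed the threshold.

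The procedure was tested on simulated data, 14244 genes with 200 changed. edgeR called 2 of 49 tested genes changed 1.5-fold, 20 of 50 changed 2-fold, 42 of 45 changed 4-fold and 45 of 46 changed 8-fold, with 5 unchanged genes called. DESeq2 called 5, 27, 44 and 45 of the same genes, with 24 unchanged genes called.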

Results

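Gene expression was measured in the livers of 10 mice, 5 given napabucasin at 20 mg per kg daily for 7 days and 5 given vehicle, to find genes and pathways of the liver and its microenvironment that the drug affects. Library totals were 14124484 to 17759967 counts in vehicle and 15364342 to 17369118 counts in napabucasin livers. Mitochondrial genes took 9.79% ± 5.21 of counts in vehicle (SD, n = 5) and 13.2% ± 4.43 in napabucasin livers (SD, n = 5). Log2 CPM correlated at 0.927 to 0.974 among vehicle libraries, 0.908 to 0.973 among napabucasin libraries and 0.887 to 0.969 between groups.

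No single gene passed the threshold, but genes of lymphocytes and interferon responses had the smallest p-values on the higher side, and Cyp7a1 of bile acid synthesis and Dbp of the clock output were among the 5 with the smallest on the lower side. edgeR's quasi-likelihood test called 0 of 14244 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.0644. At an unadjusted p under 0.05 it gave 1331 higher and 830 lower genes, 2161 together, where chance alone gives 712 on average. Among 100 splits of the libraries, the real one included, 5 gave as many and the highest other gave 3240, so chance was not excluded. The higher and lower counts were 867 and 457 without vehicle replicate 5, 852 and 580 without napabucasin replicate 1, 940 and 458 without napabucasin replicate 2 and 929 and 522 without vehicle replicate 3. With 1 surrogate variable they were 554 and 426, and with a clock covariate chosen after the data were seen 629 and 202. DESeq2 called 233 genes (166 higher, 67 lower) and limma-voom with quality weights called 132 (98 higher, 34 lower), with 85 in both. Without vehicle replicate 1, edgeR called 18 genes, 14 higher and 4 lower. With the replicate block edgeR called 0 genes, and 1675 genes were higher and 1255 lower at an unadjusted p under 0.05. With library size as the only scaling, these were 1407 higher and 361 lower.

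The 5 genes with the smallest p on the higher side, none past the threshold, were Gimap3, Ighd, Gbp9, Trbc1 and Sp100. Gimap3, a GTPase of lymphocytes (chromosome 6, 48764464 to 48770851, GRCm38), measured 7.09 ± 1.13 CPM in vehicle and 18.5 ± 3.99 CPM in napabucasin livers (SD, n = 5 each), a log2 fold change of 1.38 (SE 0.20, edgeR adjusted p = 0.0644). Ighd, the constant region of IgD on naive B cells (chromosome 12, 113406604 to 113416324), measured 5.19 ± 1.08 and 20.2 ± 8.75 CPM, a log2 fold change of 1.96 (SE 0.29, edgeR adjusted p = 0.0644). Gbp9, an interferon-induced GTPase (chromosome 5, 105077630 to 105139539), measured 18.6 ± 3.39 and 42.7 ± 9.77 CPM, and Sp100, a nuclear body protein (chromosome 1, 85649988 to 85709998), 21.8 ± 4.74 and 45.2 ± 8.26 CPM. Trbc1, a T cell receptor constant region (chromosome 6, 41538218 to 41539881), measured 1.61 ± 0.54 and 5.10 ± 1.16 CPM.

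On the lower side the smallest p-values, likewise not past the threshold, belonged to Cyp7a1, Tbx3, Dbp, Tmtc2 and Rnd2. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275633), measured 44.2 ± 24.4 CPM in vehicle and 7.29 ± 5.99 CPM in napabucasin livers, a log2 fold change of -2.61 (SE 0.48, edgeR adjusted p = 0.157). Dbp, a transcription factor of the clock output (chromosome 7, 45705088 to 45710203), measured 13.5 ± 9.42 and 1.74 ± 0.66 CPM, a log2 fold change of -2.95 (SE 0.57, edgeR adjusted p = 0.157). The transcription factor Tbx3 had a log2 fold change of -1.28 and Tmtc2 of -1.43. Rnd2, a small GTPase, measured 16.6 ± 4.26 and 8.30 ± 1.38 CPM.

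**Figure D1:**
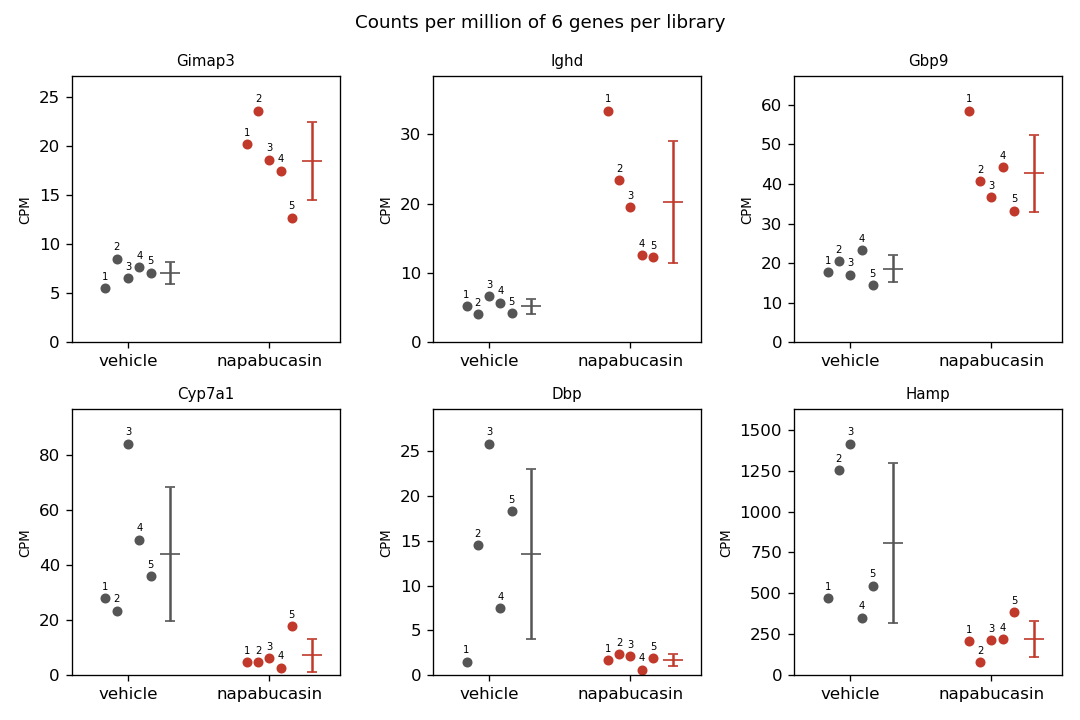
CPM of 6 genes in each library, on linear axes from 0, with replicate numbers beside the points and the group mean ± SD (n = 5) as a bar. Dbp in vehicle replicate 1 was at 1.54 CPM, within the napabucasin range of 0.641 to 2.33 CPM.

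Camera placed 24 of 58 lists past the threshold, 16 higher and 8 lower. With an estimated correlation 0 of the 24 calls held, and the smallest adjusted p was 0.285. No member of these lists passed the threshold over all genes tested, so the member counts that follow are adjusted over the list alone. Fry's directional test, which asks whether a list's genes move on balance one way, passed for 3 lists (T cell, adjusted p = 0.0199, interferon gamma, adjusted p = 0.0199, and B and plasma cell, adjusted p = 0.0402). Its mixed form passed for 7, among them the integrated stress response list, which camera did not call.

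Lymphocyte lists rose by camera. All 20 measured T cell genes lay higher in napabucasin livers, with a median log2 fold change of 1.04, and 9 passed adjusted over the list alone (camera adjusted p = 1.38e-10, adjusted p = 0.285 with an estimated correlation). The T cell score was -0.469 ± 0.157 in vehicle and 0.469 ± 0.40 in napabucasin libraries (SD, n = 5 each, exact permutation p = 0.0079, and 0.197 adjusted over the 58 lists). No list had a smaller adjusted permutation p, so none passed by this test. The smallest p it can give, 0.0079, was reached by 2 lists. Adjusted over 58 lists, that value passes only if many lists lie near it, so the lack of calls says little. Cd3d, a chain of the T cell receptor complex, measured 0.615 ± 0.256 and 2.44 ± 0.741 CPM, and Trbc2 2.28 ± 1.09 and 5.78 ± 1.51 CPM. Of 19 B and plasma cell genes 16 lay higher, the median was 0.91, and 10 passed higher and 1 lower adjusted over the list alone (adjusted p = 0.445 with an estimated correlation). Cd22, an inhibitory receptor of B cells, had a log2 fold change of 1.42 (SE 0.28). NK and cytotoxic genes had a median of 0.89 over 17 genes, of which 6 passed adjusted over the list alone (adjusted p = 0.445 with an estimated correlation); granzyme B (Gzmb) had a log2 fold change of 1.19 and Il2rb of 0.90. Ccl21a, a chemokine of lymphoid stroma chosen after its values were seen, had a log2 fold change of 2.36 (edgeR unadjusted p = 0.000928).

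Interferon lists rose by camera as well. The type I interferon list lay higher in all 33 genes, with a median of 0.79 and 18 passing adjusted over the list alone (camera adjusted p = 2.55e-11, adjusted p = 0.470 with an estimated correlation). The score of napabucasin replicate 2, -0.260, lay within the vehicle range of -0.672 to -0.0491, and the other napabucasin libraries lay above that range. Mx1, Ifit3 and Ifit2, antiviral effectors, had log2 fold changes of 1.51 (SE 0.36), 1.06 (SE 0.24) and 1.10 (SE 0.27). The interferon gamma and antigen presentation list lay higher in 31 of 37 genes, with a median of 0.47 and 11 passing adjusted over the list alone (adjusted p = 0.285 with an estimated correlation). Gbp3 and Gbp4 had log2 fold changes of 0.86 and 1.17. For MHC class II the median was 0.46 over 10 genes, 4 of which passed adjusted over the list alone (adjusted p = 0.518 with an estimated correlation), and 0.30 without vehicle replicate 1. H2-Ob and H2-DMb2, which act in peptide loading, had log2 fold changes of 1.53 and 1.01.

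**Figure D2:**
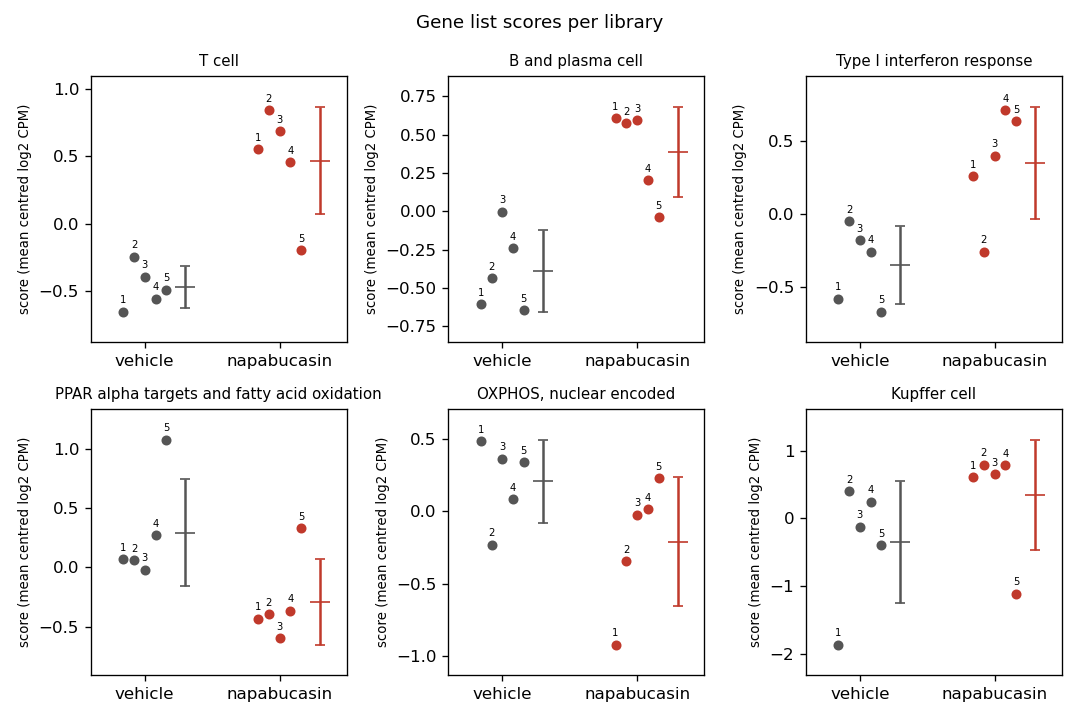
Scores of 6 gene lists in each library, the mean of centred log2 CPM over the list, with replicate numbers beside the points and the group mean ± SD (n = 5) as a bar. The T cell score of napabucasin replicate 5, -0.197, lay closest to the vehicle libraries, whose highest was -0.246.

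Stromal and resident cell lists rose by camera with more dependence on single libraries. Extracellular matrix genes had a median of 0.50, 7 of 37 passing adjusted over the list alone (adjusted p = 0.518 with an estimated correlation), and 0.29 without napabucasin replicate 4. Stellate cell and fibroblast genes had a median of 0.61, 7 of 21 passing (adjusted p = 0.518 with an estimated correlation), and 0.25 without napabucasin replicate 4. Postn, a matrix protein, had a log2 fold change of 1.07, Col4a1 of 0.77, the pericyte receptor Pdgfrb of 0.81 and Col14a1 of 0.82. Sinusoidal endothelial genes had a median of 0.65 over 22 genes with 0 passing adjusted over the list alone (adjusted p = 0.518 with an estimated correlation), 0.42 without vehicle replicate 3 and 0.43 without vehicle replicate 5; Mrc1, the mannose receptor, had a log2 fold change of 1.11 and Pecam1 of 0.77. The list of Kupffer cells, resident macrophages, held Clec4f (log2 fold change 1.07) and Cdh5 (0.67), the latter also in the sinusoidal endothelial list. The Kupffer cell median was 0.65 over 16 genes with 0 passing adjusted over the list alone (adjusted p = 0.619 with an estimated correlation). That call ended without vehicle replicate 1 (median 0.40, adjusted p = 0.154). Kupffer cell scores were lowest in vehicle replicate 1 (-1.86) and napabucasin replicate 5 (-1.11). Proliferation genes, with Ccnb2 at 1.71 and Kif11 at 1.13, had a median of 0.39 (adjusted p = 0.470 with an estimated correlation).

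Some lists of hepatocyte metabolism fell by camera, those of fatty acid oxidation, the urea cycle and oxidative phosphorylation. Others did not pass, among them gluconeogenesis (camera adjusted p = 0.104), cholesterol synthesis (0.224), glycolysis (0.300) and fatty acid synthesis (0.935). PPAR alpha targets and fatty acid oxidation genes lay lower in 37 of 41 genes, with a median of -0.61 and 12 passing adjusted over the list alone (camera adjusted p = 1.26e-10, adjusted p = 0.518 with an estimated correlation). The thioesterase gene Acot3 measured 58.7 ± 54.3 and 14.7 ± 5.82 CPM, a log2 fold change of -1.99, and -1.26 without vehicle replicate 5, which was at 152 CPM. Cpt1a, which admits fatty acids to mitochondria, measured 317 ± 101 and 167 ± 43.0 CPM. Slc25a20 and Acot2 had log2 fold changes of -0.76 and -0.94. Urea cycle and amino acid genes had a median of -0.32, with 3 of 37 passing adjusted over the list alone (adjusted p = 0.518 with an estimated correlation). Mat1a, which makes S-adenosylmethionine, measured 2704 ± 587 and 1344 ± 392.2 CPM, and the ornithine carrier Slc25a15 263 ± 52.2 and 157 ± 26.5 CPM. Hepatocyte identity genes had a median of -0.30 (adjusted p = 0.602 with an estimated correlation), with Onecut1 at -1.17 and Cebpa at -0.68; 0 of 29 passed adjusted over the list alone. Its lowest scores were in vehicle replicate 2 (-0.361) and napabucasin replicates 2 (-0.358) and 1 (-0.350), the 3 libraries with the highest share of counts in rRNA genes (0.912%, 1.09% and 1.09%).

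Nuclear genes of oxidative phosphorylation (OXPHOS) lay lower in all 45 measured, with a median of -0.40 and 0 passing adjusted over the list alone (adjusted p = 0.602 with an estimated correlation). Without napabucasin replicate 1 the median was -0.24. Sdhd had a log2 fold change of -0.87 and Uqcrfs1 of -0.50. Ribosomal protein genes had a median of -0.27, and -0.15 without napabucasin replicate 1 (adjusted p = 0.602 with an estimated correlation); Rps28 had a log2 fold change of -0.62 and Rpl3 of -0.63. Napabucasin replicates 1 and 2 had ribosomal scores of -0.714 and -0.337 and OXPHOS scores of -0.919 and -0.343, where replicates 3, 4 and 5 had 0.0775, 0.278 and -0.0511 and -0.0224, 0.0147 and 0.227. The share of counts in rRNA genes was 1.09% in each of those 2 libraries and 0.195% to 0.912% in the other 8. It was taken over all genes whose biotype names rRNA, so mitochondrial and other rRNA were not told apart. Napabucasin replicate 1 and vehicle replicate 1 held the highest mitochondrial shares, 19.9% and 19%.

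Acute phase genes, which the liver makes under inflammatory cytokines, fell by camera as a list; 27 of 29 genes lay lower, with a median of -0.40 and 1 passing adjusted over the list alone (adjusted p = 0.602 with an estimated correlation); the median was -0.25 both without vehicle replicate 2 and without vehicle replicate 3. The gene that passed, Hamp, encodes the iron hormone hepcidin and measured 807 ± 488 and 222 ± 109 CPM. Serpina3m, Saa2 and Saa1 had log2 fold changes of -0.77, -1.20 and -1.09; without vehicle replicate 3 those of Saa2 and Saa1 were -0.63 and -0.62. Female-biased genes had a median of -0.55 (camera adjusted p = 0.0495, adjusted p = 0.619 with an estimated correlation), with Cyp17a1 at -2.02, and -0.32 without vehicle replicate 5 (adjusted p = 0.182). That call held in only 3 of the 10 fits with 1 library left out, those without vehicle replicate 2 and without napabucasin replicates 2 and 5.

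The list of STAT3 targets, the pathway for which the drug is named, did not pass: its median was 0.11 over 28 genes (camera adjusted p = 0.454), with 0 passing adjusted over the list alone. Il10ra, Ccnd1 and Fos had log2 fold changes of 0.98, -0.68 and 1.59. Without napabucasin replicate 2 that of Fos was 0.98. The acute phase list, fixed beside the STAT3 list among those of drug pathways, did fall by camera. Its median was -0.40 (camera adjusted p = 0.000286, adjusted p = 0.602 with an estimated correlation). Stat3 measured 108 ± 30.0 and 91.6 ± 8.81 CPM, a log2 fold change of -0.23 (95% interval -0.67 to 0.21), which ran from -0.375 without vehicle replicate 1 to -0.107 without vehicle replicate 3, and the feedback inhibitor Socs3 had -0.54 (-1.99 to 0.90). NRF2 targets, genes of the response to quinones and oxidants, had a median of -0.10 over 36 genes (camera adjusted p = 0.721). Gclc and Osgin1 had log2 fold changes of 0.78 and 0.98, and Srxn1 of -0.49. Nqo1, the reductase of quinones, measured 10.9 ± 4.65 and 9.31 ± 2.66 CPM, a log2 fold change of -0.22 (-0.88 to 0.45), which ran from -0.407 without vehicle replicate 2 to -0.0439 without vehicle replicate 3.

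Drug-metabolizing genes did not pass in edgeR's test of all libraries. By camera the lists of CAR and PXR targets and of phase II conjugation did not pass either (adjusted p = 0.242 and 0.171). Without vehicle replicate 2 both passed lower by camera (median -0.33, adjusted p = 0.000116, and median -0.34, adjusted p = 3.85e-05). Both also passed lower with the clock covariate (camera adjusted p = 0.0235 and 0.000788), where only vehicle replicate 1 overlapped the napabucasin clock scores. Phase II conjugation did so without napabucasin replicate 5 (camera adjusted p = 0.0365). Por, the electron donor of microsomal P450 enzymes, had a log2 fold change of -0.63 (95% interval -1.22 to -0.04, edgeR adjusted p = 0.315). Cyp3a11 had -0.14 (-0.79 to 0.51), Cyp2b10 0.47 (-1.12 to 2.07), Cyp1a1 0.00 (-1.03 to 1.03) and Cyp1a2 -0.16 (-1.17 to 0.84). Of the clock list, which did not pass (camera adjusted p = 0.320), Dbp, Hlf (-1.06), Cry1 (1.27) and Arntl (1.11) passed adjusted over the list alone. In the bile acid list, which did not pass (camera adjusted p = 0.454), Cyp7a1 passed adjusted over the list alone, while Cyp8b1 (-1.74) and Nr0b2, a repressor of Cyp7a1 (0.92), did not.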

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

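Of 208 groups of 5 values examined, 16 held a library far from the other 4, where chance gives about 10.4; the ratio is the gap to the nearest library over the whole range, with a critical value of 0.71. Of the tests in this part, those on gene length and the DESeq2 splits were chosen before their results were seen, and the tests on lymphocytes, the clock, single libraries, the rRNA share and the other splits after, as was the exchange of labels within pairs.

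Vehicle replicate 1 stood apart in its mitochondrial share (19% against 7.03% to 8.78%, ratio 0.854), its mitochondrially encoded score (1.32 against -0.739 to -0.411, ratio 0.841), Cyp1a1 (4.70 against 0.843 to 1.79 CPM, ratio 0.754) and Arntl (28.5 against 8.24 to 11.7 CPM, ratio 0.829). Vehicle replicate 2 stood apart in its periportal score (-0.324, ratio 0.714), Socs3 (148 CPM, ratio 0.711) and Mrc1 (90.7 CPM, ratio 0.802). Vehicle replicate 4 was high in its matrix score (0.249, ratio 0.814), and vehicle replicate 5 in fatty acid oxidation (1.08, ratio 0.736). Napabucasin replicate 4 was high in its matrix score (0.692, ratio 0.748). Napabucasin replicate 5 stood apart in MHC class II (-0.397, ratio 0.764), Kupffer cell (-1.11, ratio 0.903) and fatty acid oxidation scores (0.329, ratio 0.75), and in Cyp7a1 (17.8 CPM, ratio 0.779), Por (253 CPM, ratio 0.825) and Cdh5 (17.1 CPM, ratio 0.712).

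The counts of calls were set against other splits of the 10 libraries. Each number of splits given includes the real one. By edgeR the real split gave 0 genes, so all 100 splits drawn had to give as many and this comparison tests nothing; the highest other gave 394. At an unadjusted p under 0.05 the real split gave 2161 genes, 5 of 100 splits gave as many, and the highest other gave 3240, so chance was not excluded. For lists past the camera threshold, 35 of 100 splits gave the real 24 or more, with a highest other of 45. With DESeq2 4 of 40 splits gave the real 233 genes or more, and the highest other gave 1519. Chance was not excluded for the lists or for DESeq2 either. One split gave the highest counts of genes with both tools, and with DESeq2 its 1519 genes are several times the real 233, which points to a structure of the samples that was not tested further. It is the real split with vehicle replicate 1 and napabucasin replicate 4 exchanged, so it shares most of its groups with treatment. It also parts the libraries by mitochondrial share, 10.3% to 19.9% of counts in the group with vehicle replicate 1 and 7.03% to 9.03% in the other. Whether that share accounts for its counts was not tested. Among splits parting all 5 same-numbered pairs, the highest other was 1024 genes at an unadjusted p under 0.05 in 12 splits, and 1 gene by DESeq2 in 8 splits. For lists, 3 of the 12 reached the real 24, with a highest other of 33; with the replicate block edgeR called 0 genes.

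The higher lymphocyte lists were weighed against 4 technical explanations, tested on the T cell list; the B and NK lists were not tested this way. A lower hepatocyte share was first weighed with the cholangiocyte list. The T cell score rose by 1.05 more than the cholangiocyte score between groups (exact permutation p = 0.0079 without regard to pairs), while cholangiocyte genes had a median of -0.19. Within the 5 same-numbered pairs that difference was higher in all 5, from 0.432 to 1.57 (SD 0.456). An exact permutation test within pairs gave p = 0.0625, the smallest that 5 pairs can give, so by that test it could not pass the threshold. With the replicate block the T cell list had a median of 1.01. Cholangiocytes were the only one of 4 resident non-hepatocyte lists whose score did not rise. Sinusoidal endothelial, Kupffer and stellate scores rose by 0.698, 0.689 and 0.468 (exact permutation p = 0.0873, 0.254 and 0.0317). Hepatocyte identity fell by 0.297 (exact permutation p = 0.127). These are the directions a lower share would give. The T cell score exceeded the endothelial, Kupffer and stellate scores by 0.24 (exact permutation p = 0.556), 0.249 (exact permutation p = 0.524) and 0.47 (exact permutation p = 0.111). It exceeded the mean of the 4 by 0.503 (exact permutation p = 0.0159). The stellate score itself exceeded the cholangiocyte score by 0.584 (exact permutation p = 0.00794), so these types did not rise alike. Cholangiocyte genes alone thus cannot stand for the other cells, and a lower share as part or all of the cause stays open. Carried-over lymph node remains open: the T cell minus stroma difference was -0.742 (exact permutation p = 0.18). The stroma score was higher (exact permutation p = 0.0238), and so in all 5 same-numbered pairs (exact permutation within pairs p = 0.0625). But that score rests on 2 of 7 genes, Ccl21a and Cxcl13, and Glycam1 had 0 counts in every library. The minimum of 3 genes for a verdict was applied to this outcome after its value was seen. More blood could not be excluded (difference 0.624, exact permutation p = 0.57), nor clock phase, since after regression on the clock score the T cell difference was 0.597 (exact permutation p = 0.063) against 0.938 before. An effect of the drug on liver lymphocytes stays open beside these.

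Clock genes of opposite phase differed in opposite directions: a set of 9 with Dbp had a median log2 fold change of -0.45 (exact permutation p = 0.0556 of its score) and a set of 5 with Arntl had 1.02 (exact permutation p = 0.0397). The score of the Dbp set minus that of the Arntl set differed by -1.58 (exact permutation p = 0.032 without regard to pairs). Within the 5 same-numbered pairs it was lower in all 5, from -2.42 to -0.0235 (SD 0.936, exact permutation within pairs p = 0.0625). The difference may reflect another hour of sampling. That and an effect of the drug or of feeding cannot be told apart, since no label used here gives the hour. Vehicle replicate 1, with a clock score of -1.02, lay among the napabucasin libraries, which ran from -1.23 to -0.203.

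Lower OXPHOS and ribosomal lists were weighed against gene length, single libraries and RNA quality. The length was the deposited gene length, which can differ from that of the transcripts, so short transcripts were tested only indirectly. The OXPHOS median of -0.40 lay at percentile 0.01 of 10000 random lists matched on length and expression, the lowest they can give. The median of those lists was -0.18. Their genes were drawn separately, while OXPHOS genes move together (estimated correlation 0.734), which widens the spread of a list median. The percentile therefore cannot decide whether length and expression class account for all of the fall. The ribosomal median lay at percentile 5.6, inside the matched lists, so length or expression class may account for it. Without napabucasin replicate 1 the score differences were -0.239 for OXPHOS (exact permutation p = 0.23, -0.417 with it) and -0.158 for ribosomal genes (exact permutation p = 0.206, -0.299 with it), which leaves the part of that library open. Napabucasin replicates 1 and 2 had the lowest scores, -0.919 and -0.343 for OXPHOS and -0.714 and -0.337 for ribosomal genes, and the highest share of counts in rRNA genes, 1.09% each against 0.195% to 0.912% in the others; vehicle replicate 2, at 0.912%, had an OXPHOS score of -0.23 and a ribosomal score of 0.139. Without both napabucasin libraries the differences were -0.135 for OXPHOS (exact permutation p = 0.464) and -0.0481 for ribosomal genes (exact permutation p = 0.589). After regression on the rRNA share they were -0.133 for OXPHOS (exact permutation p = 0.294) and -0.117 for ribosomal genes (exact permutation p = 0.421). The regression held no treatment term, and the share was itself highest in napabucasin replicates 1 and 2. It therefore cannot tell the share from treatment, and RNA quality as a cause of both falls stays open. The share did not set mitochondrial rRNA apart from other rRNA, so it is only an indirect measure of RNA quality. Of the 24 lists called, 6 fell to less than 50% of their score difference in that regression: these 2, hepatocyte identity (-0.297 to -0.0939), female-biased (-0.401 to -0.05), Kupffer cell (0.689 to 0.339) and inflammatory genes (0.321 to 0.149). Among the others, PPAR alpha targets went from -0.584 to -0.385 (exact permutation p = 0.175) and urea cycle genes from -0.318 to -0.181 (exact permutation p = 0.214). The T cell difference was 0.677 (exact permutation p = 0.00794).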

How the results depend on the processing

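The alternatives that left out a pair of libraries and the clock covariate were chosen after seeing the data. Of the vehicle libraries only replicate 1 had a clock score (-1.02) within the napabucasin range of -1.23 to -0.203. Fits with the clock covariate may therefore rest largely on that library. The count of 0 genes by edgeR held with size factors (RLE), the stricter filter, the non-robust test, protein-coding genes, the replicate block, 1 surrogate variable and the clock covariate. A required absolute log2 fold change above 1 could give no other count. Limma on log2(FPKM + 1), with or without a filter, also called 0 genes. DESeq2 called 166 higher and 67 lower genes (233), and limma-voom 98 and 34 (132). Without a low-count filter there were 15 and 4 (19), with library size only 1 and 0 (1), and with limma on log2(FPKM + 0.1) 0 and 1 (1). Leaving out 1 library gave 0 to 14 higher, 0 to 4 lower and 0 to 18 changed genes, the highest without vehicle replicate 1; without napabucasin replicate 5 there were 3. Leaving out vehicle 1 and 2 gave 41 and 11 (52), vehicle 1 and napabucasin 5 gave 10 and 4 (14), and vehicle 1 and napabucasin 1 gave 6 and 1 (7). The cause was not tested. At 14124484 to 17759967 counts per library and this spread, edgeR called 20 of 50 simulated 2-fold changes, so smaller changes are mostly below what these libraries can show.

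The 24 list calls (16 higher, 8 lower) fell to 0 (0 and 0) with an estimated correlation and to 3 (3 and 0) with fry's directional test. Fry's mixed test passed for 7 lists. Among these was the integrated stress response list (fry mixed adjusted p = 0.00112), which was not among the 24 (camera adjusted p = 0.242). With 1 surrogate variable 3 lists were lower, and 14 were lower without vehicle 1 and 2. Leaving out 1 library gave 14 to 19 higher, 7 to 15 lower and 22 to 31 in all, with 15 lower without vehicle replicate 2 and 13 without napabucasin replicate 5. For the 24 lists called and the STAT3 and NRF2 lists, 481 of 572 results over the alternatives kept their direction and side of the threshold, 81 lost it, 2 gained it and 8 reversed. Among the 32 other lists, 65 of 702 results passed the threshold, in 19 lists; immune checkpoints and metastatic niche, both with an adjusted p of 0.071, were among them. With the replicate block 25 lists passed, the metastatic niche list entering with an adjusted p of 0.0134, and no other list or named gene call changed.

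STAT3 targets passed only with the clock covariate (median 0.27, adjusted p = 0.0207), and ran from -0.02 to 0.23 with 1 library left out. NRF2 targets passed only with the clock covariate, lower (median -0.17, adjusted p = 0.0307), and ran from -0.16 to 0.0107 with 1 library left out. Vehicle replicate 1 had the lowest STAT3 score (-0.313) and the highest NRF2 score (0.268) of all libraries, so both calls may lean on it. The NRF2 test turned with 1 surrogate variable (median 0.14), without vehicle replicate 1 (median -0.08, test direction only), without napabucasin replicate 1 (0.0107) and without vehicle 1 and napabucasin 1 (0.00622). The direction also turned for 3 called lists with 1 surrogate variable, mitochondrially encoded (-0.29), female-biased (-0.10, test direction only) and ribosomal (-0.00138, test direction only), and for mitochondrially encoded with the clock covariate (-0.36). The cause was not tested.

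Of 1857 results for named genes, 1722 were the same, 100 passed the threshold and 35 reversed, none of these past it in the main test. Cyp1a1 turned to -0.00173 with RLE, -0.0202 without a filter, -0.00676 with DESeq2, -0.00584 with 1 surrogate variable, -0.00145 with protein-coding genes and -0.84 with the clock covariate, and to -0.02, -0.15, -0.18 and -0.12 without vehicle replicates 2, 3, 4 and 5, and -0.00787 and -0.27 without napabucasin replicates 2 and 4, with a range of -0.27 to 0.59 over the libraries left out. Cyp1a2 turned to 0.00957 with library size only, 0.14 with limma-voom, 0.15 with each of the 3 FPKM settings, 0.13 with the replicate block, 0.30 with 1 surrogate variable, 0.0764 and 0.00593 without vehicle replicates 1 and 5 (range -0.44 to 0.0764), and 0.24 without vehicle 1 and napabucasin 1. Socs3 turned to 0.16 with limma-voom, 0.44 without vehicle replicate 2 (range -0.89 to 0.44), 0.40 without vehicle 1 and 2 and 0.63 with the clock covariate. Cyp2b10 turned to -0.0212 with limma-voom and -0.38 without napabucasin replicate 2 (range -0.38 to 0.90), Cyp3a11 to 0.10 without vehicle replicate 4 (range -0.31 to 0.10), and Nqo1 to 0.00941 with 1 surrogate variable and 0.00173 without vehicle 1 and napabucasin 1. With the clock covariate Stat3 turned to 0.22, Serpina3m to 0.11, Saa2 to 0.0896 and Saa1 to 0.0644. The cause was not tested.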

Other observations

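The family grouping and its tests were chosen after the data were seen. Genes were grouped by the stem of their symbol into 402 families with at least 5 tested members, and camera with the preset correlation called 30, while 0 were called with an estimated correlation (smallest adjusted p = 0.816). The Ifi family, interferon-inducible genes, lay higher in all 18 members with a median log2 fold change of 1.01, and the Gbp family in all 11 with a median of 1.01. The Gimap family of lymphocyte GTPases lay higher in 8 of 9 members (median 0.65), the Slfn family in all 6 (median 0.90), the Oas family in all 6 (median 1.01) and the collagen genes (Col) in 24 of 27 (median 0.63). On the lower side, the Pex genes of peroxisome assembly lay lower in 15 of 16 members (median -0.34), the Cox genes in all 21 (median -0.27) and the mitochondrial ribosomal Mrpl genes in 45 of 49 (median -0.21). Members of one family can share reads and are not independent.

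Among lists not described above, immediate early genes had a median of 0.55, dendritic cell genes of 0.47, angiogenesis genes of 0.31, inflammatory genes of 0.22 and mitochondrially encoded genes of 0.24, all past the camera threshold and none with an estimated correlation (adjusted p = 0.518, 0.445, 0.518, 0.619 and 0.679). With 1 library left out, the inflammatory call held in 5 of 10 fits and the mitochondrially encoded call in 3 of 10. The inflammatory median ran from 0.12 without vehicle replicate 5 to 0.53 without vehicle replicate 4, and was 0.48 without vehicle replicate 2 and 0.42 and 0.33 without napabucasin replicates 5 and 1. The mitochondrially encoded median ran from -0.00077 without napabucasin replicate 1 to 0.79 without vehicle replicate 1, and was 0.13 without vehicle replicate 2 and 0.36 without napabucasin replicate 4. Periportal genes had a median of -0.38 (adjusted p = 0.518 with an estimated correlation). Neutrophil genes (0.35) and monocyte genes (0.26) did not pass in the main camera test. With no library left out both passed higher with the clock covariate (camera adjusted p = 6.26e-05 and 0.000798), and monocyte genes with 1 surrogate variable (0.0196). Vehicle replicate 1, the only vehicle library within the napabucasin clock range, had the lowest neutrophil (-1.03) and monocyte (-1.14) scores. The calls with the clock covariate may rest on that library. Neutrophil genes also passed without vehicle replicate 3 (adjusted p = 0.0395). Monocyte genes did so without vehicle replicates 3 (0.0309) and 4 (0.00782) and napabucasin replicates 1 (0.0493) and 5 (0.0224). Median and mean differ in sign for hepatocyte injury (-0.0037 and 0.02, test higher), fatty acid synthesis (-0.14 and 0.03, test lower), growth hormone (-0.03 and 0.03, test lower) and retinol genes (-0.09 and 0.20, test higher), none past the threshold. Xist had 3326 to 13893 counts and 4 Y-linked genes together 0 to 6 counts in each library.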
